A study of Ictalurus punctatus with 6 samples.

How the data were processed

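The data were one-colour microarray measurements of anterior (head) kidney, the main blood-forming and immune organ of bony fish, from channel catfish (Ictalurus punctatus). Per the labels, 3 samples came from sham-vaccinated fish and 3 from fish that were given an attenuated Edwardsiella ictaluri vaccine and, 28 days later, challenged by immersion with virulent E. ictaluri and sampled 48 h after the challenge. Each sample was a pool of 5 fish, and the labels gave the pools as separate samples, so the spread between pools was the error of every comparison. The labels called the controls sham vaccinated while the design text called them neither vaccinated nor challenged, and some descriptions of challenged samples counted fewer replicates than their titles. The titles were followed, which gave 2 groups of 3.

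Total RNA was extracted with a column kit and Cy3-labelled by the array manufacturer, per the labels' protocols. The array carried 3 probes per sequence and 2 copies of each probe set, per the series design text, which gave 65182 genes per chip. The table used here held 53801 sequences with 2 values per array. The values were summarised by the authors with RMA (robust multi-array average), per the submitters' processing notes, which gave no version and no software. RMA corrects background, makes the distributions of all arrays alike and summarises the probes of a set. The deposited values were intensities on a linear scale, from 6.27 to 65382, with array medians between 594 and 652. The design had assumed log2 values, so log2 was taken of the deposited intensities before any test, and the copies of a sequence were averaged on the log2 scale. The copies of an array correlated with r between 0.993 and 0.994 across sequences. The standard deviation of a single copy, estimated from the difference between copies, was between 0.243 and 0.277 on the log2 scale. Files of single arrays, which hold scanner intensity per the file headers with no normalisation evident, were used for the 3 challenged arrays only; those of the control arrays were not analysed here. They gave the sequence descriptions and were set against the same array's column of the table, with r between 0.949 and 0.956, and entered no comparison of groups. Each challenged array had a slide of its own, so slide could not be tested as a batch.

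Gene names were taken from the sequence descriptions in the deposited files of single arrays. A name was usable when it came from a vertebrate and was not a clone, hypothetical, unknown or uncharacterised entry. A name given by protein similarity also had to cover at least 20% of the protein and not be called weakly similar. This left 12098 of the 53801 sequences with 5536 distinct names. The sequence identifiers did not match the reference gene table, and no genome was used here, so no coordinates are given and sequences are named by array identifier. Several sequences can belong to 1 gene.

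The comparison was challenged minus control on the log2 scale, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no filter, no further normalisation, no block and equal weights. The moderated test was two-sided. P values were adjusted by Benjamini-Hochberg over all 53801 sequences, and an adjusted p below 0.05 was the threshold. Errors given with fold changes are limma standard errors. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

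Gene lists were written before the data were examined, as were the design, the rule for named genes and most alternatives. The lists covered acute phase and iron proteins, complement, pattern recognition, cytokines and chemokines, interferon response, MHC class I and class II presentation, proteasome, heat shock and ER stress, apoptosis, cell cycle and DNA replication, ribosomal proteins, oxidative phosphorylation, and markers of T cells, B and plasma cells, cytotoxic and NK cells, macrophages, neutrophils, erythroid cells, thrombocytes and coagulation, renal tubule, interrenal steroid synthesis, chromaffin cells, skeletal muscle, hepatocytes and exocrine pancreas. Of the 26 lists, 25 had at least 1 matched name and 24 had the 5 genes needed for a test. A gene was represented by its sequence with the highest mean. Where members were matched by a general name pattern, as in the proteasome and oxidative phosphorylation lists, each distinct name counted as a gene. Several such names can belong to 1 gene. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists; camera compares a list with all other sequences. Camera with a correlation estimated per list and fry were alternatives, and the ranges given for lists cover those that used camera. The p of fry tests whether the genes of a list move, on balance, one way, and compares them with no other genes. Members are counted at the threshold over all sequences and after adjustment over the list alone.

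Genes named in the text were the 12 with the largest rise and the 12 with the largest fall among sequences with 1 usable name that passed the threshold and whose 3 challenged pools all lay on one side of the 3 controls, taking for each gene the sequence with the smallest p; up to 4 members with the smallest p of each tested list; and, whatever their values, hepcidin, IL-1 beta, IL-8, TNF, interferon gamma, inducible nitric oxide synthase, IgM heavy chain, IL-10, IL-17, CD8 and CD4. No usable array name matched inducible nitric oxide synthase, IL-10, IL-17 or CD8. Values of some genes that the rule names are not reported here. The rule gave 108 results, a gene being counted once for each sequence that represented it.

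The steps were tested on simulated data. In 5 simulations on 53801 sequences with 200 changed in each, limma recovered 382 of 500 changes of 2 on the log2 scale (76.4%) and 15 of 500 changes of 1 (3%), and 4.8% of the calls were false. A list shifted by 0.5 was called in 5 of 5 simulations, and 0 of 115 unshifted lists were called by camera at the same threshold. The simulated sequences were independent of each other, while the estimated correlation within the proteasome list, for one, was 0.487. The simulated lists therefore cannot show how often camera at the preset correlation calls an unshifted list of correlated genes. The test of words in gene names found 25 of 25 words set higher. With so few changed sequences the adjusted threshold was stricter than in the data, so these shares do not carry over to them. The number of arrays limits the precision.

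Alternatives were a replicate block, renewed quantile normalisation, centring on array medians, filters on dim sequences at the median and at the 25th percentile, an intensity trend with robust eBayes, array weights, each pool left out in turn, other thresholds, an ordinary linear model without eBayes, 1 sequence per gene name, the mean or median over all sequences of a gene and other list tests. Testing each copy by itself and representing genes by a sequence below 14 on the log2 scale were added after the data were seen. All 10 splits of the 6 samples into groups of 3 were fitted.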

Results

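The data were transcript levels in the anterior kidney of channel catfish, measured for 53801 array sequences in 3 control pools and 3 challenged pools of 5 fish each. Control fish were sham vaccinated. Challenged fish had been immunised with an attenuated strain of Edwardsiella ictaluri, the bacterium of enteric septicaemia of catfish, and were sampled 48 h after immersion with the virulent bacterium. Vaccination and challenge came together in every challenged pool, so the comparison gives their joint difference from the controls. Median intensities of the arrays lay between 594 and 652. Correlations across sequences on the log2 scale were 0.986 to 0.991 between pools of a group and 0.969 to 0.981 between groups. The first principal component, with 50.6% of the variance, separated the groups.

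The comparison asked which transcripts of the anterior kidney differ 48 h after challenge in vaccinated fish. IL-1 beta, the early inflammatory cytokine, rose by 4.17 ± 0.27 on the log2 scale (TC14537; n = 3 pools per group; limma adjusted p = 3.46e-04), an 18-fold change. IL-8, the chemokine that draws neutrophils, rose by 3.37 ± 0.18 (BM425301_1; adjusted p = 1.64e-04), and lysozyme c, which breaks bacterial cell walls, by 4.89 ± 0.23 (CV991030; adjusted p = 1.25e-04). That lysozyme c sequence was dim in the controls (mean 4.74), and the median over the 17 sequences of the gene was 2.11. Of 40 names of proteasome subunits 33 were called higher, but 7 without challenged pool 1 and 16 without challenged pool 3. Over the 50 names that hold the word proteasome, the median was 1.02 with all pools. It was 0.98 without challenged pool 1 and 0.99 without challenged pool 3. Camera gave the proteasome list adjusted p = 6.44e-23, with adjusted p = 0.240 with an estimated correlation. Apolipoprotein E, a lipid carrier made by macrophages, fell by 2.80 ± 0.21 (CF262783_1; adjusted p = 6.43e-04).

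Of the 53801 sequences, 5712 passed the threshold, with 3532 higher and 2180 lower in the challenged pools. In each of the 5712 the 3 challenged pools lay on one side of the 3 controls. Over all sequences, 17624 (32.8%) had groups that did not overlap, against 10% by chance. At least 2-fold differences were found in 2083 of the higher and 1185 of the lower sequences, and at least 4-fold ones in 294 and 80. Usable gene names were carried by 988 higher and 400 lower sequences, with 981 distinct names. The count was lower in each fit that left out 1 pool, which had fewer samples. It fell to 3254 without control pool 1, 3109 without control pool 2, 3338 without control pool 3, 1090 without challenged pool 1 and 2092 without challenged pool 3, and was 5292 without challenged pool 2.

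The 12 largest rises among named genes lay between 3.01 and 4.89 on the log2 scale. After lysozyme c came MFAP4, a fibrinogen-related extracellular protein, with 4.61 ± 0.24 (BM438501_1; 24.3-fold; adjusted p = 1.64e-04; 3 of its 4 sequences called). CD59, a membrane protein that blocks the complement attack complex, rose by 3.98 ± 0.27 (BM438520_1). A neurotoxin/C59/Ly-6-like sequence rose by 4.29 ± 0.27 (TC16851) and MxG by 4.14 ± 0.22 (BM494987). The chemokines SCYA107 and SCYA101 rose by 3.05 ± 0.31 and 3.01 ± 0.35, and a small inducible cytokine B6-like sequence by 3.74 ± 0.26. NF-kappa-B inhibitor zeta, a nuclear regulator induced by inflammatory signals, rose by 3.04 ± 0.21 (CK414557), and differentially regulated trout protein 1 by 3.88 ± 0.28. All 12 stayed called whichever pool was left out. Of 17 lysozyme c sequences 14 were called higher, with a median of 2.11 over all 17, as were 6 of 6 for IL-1 beta and 8 of 9 for IL-8. In 7 of the 12, lysozyme c, MFAP4, the neurotoxin/C59/Ly-6-like sequence, CD59, trout protein 1, the B6-like sequence and NF-kappa-B inhibitor zeta, the control mean lay below the 25th percentile of all sequences in the controls, 6.43, as with 4.74 ± 0.26 (SD) for lysozyme c. The size and order of those rises rest on dim signal.

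The 12 largest falls lay between -1.87 and -2.80. Apolipoprotein E was followed, among those called whichever pool was left out, by lunatic fringe, a glycosyltransferase that modifies Notch, at -2.10 ± 0.34 (CV990149; adjusted p = 0.0122). Tartrate-resistant acid phosphatase, an enzyme of osteoclasts and macrophages, fell by 1.97 ± 0.21 (CK419694_1; adjusted p = 0.00319) and alcohol dehydrogenase 1 by 1.87 ± 0.23 (BM438391_1; adjusted p = 0.00507). An alcohol dehydrogenase sequence fell by 1.91 ± 0.22 (BM438660_1; adjusted p = 0.00412), but the median over the 5 sequences of that name was 0.25. For apolipoprotein E 6 of 8 sequences were called lower, with a median of -2.78. In 4 of the 12, apolipoprotein E (5.83), cytochrome P450 2P2, cytochrome c oxidase subunit IV and NADPH oxidase 1, the challenged mean lay below 6.43, so the size and order of those falls rest on dim signal too. The 7 falls beside the 5 above were not called in every fit that left out 1 pool. CNS myelin P0-like glycoprotein (-2.16 ± 0.38) and an alpha globin sequence (-1.91 ± 0.33; median of 62 globin sequences -0.37) lost the call without challenged pool 1, with adjusted p = 0.0708 and 0.0642. The somatostatin receptor (-1.90 ± 0.39; median of 2 sequences -1.22) lost it without control pool 2 (0.0704), control pool 3 (0.0588) or challenged pool 1 (0.0656). Cytochrome P450 2P2 (-2.15 ± 0.55, up to 0.107) and NADPH oxidase 1 (-1.92 ± 0.42, up to 0.0874) lost it without any pool but control pool 1, and a gag-like sequence (-2.12 ± 0.49, up to 0.0906) without any pool but control pool 2. A cytochrome c oxidase subunit IV sequence, described as isoform 2 (-2.13 ± 0.45), lost it without pool 2 or 3 of either group (adjusted p up to 0.0772). The median over the 10 sequences named subunit IV was 0.18, but isoform labels were dropped from names, so isoforms may be mixed.

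**Figure D1:**
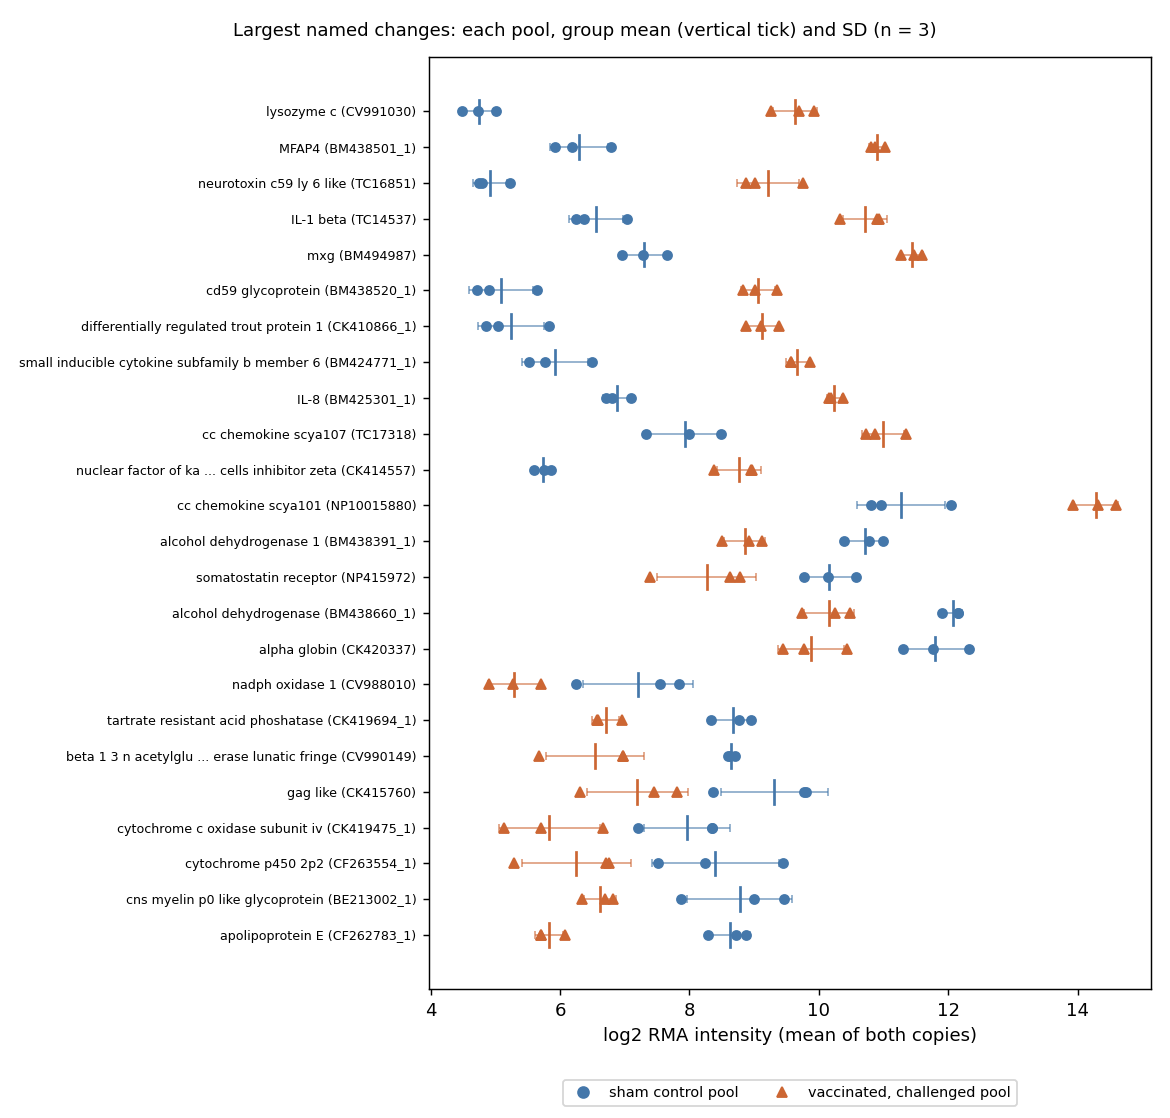
Level of the 12 named genes with the largest rise and the 12 with the largest fall in each pool, on the log2 RMA intensity scale (horizontal axis; mean of both copies of a sequence), with sequence identifiers in brackets on the vertical axis. Circles are the 3 control pools and triangles the 3 challenged pools, with vertical ticks at group means and bars of 1 SD; in each gene the 3 challenged pools lie apart from the 3 controls, as in apolipoprotein E with means of 8.63 and 5.83.

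All 40 names of the proteasome list had positive log2 fold changes, with a median of 1.11. Some of these names can belong to the same gene, so they are not 40 independent members. Of them 33 passed over all sequences and 37 when adjusted over the list alone, none lower. The count of 33 fell to 7 without challenged pool 1 and 16 without challenged pool 3, in fits with fewer samples. The size of the rise moved little. Over the 50 names that hold the word proteasome, the median was 1.02 with all pools, 0.98 without challenged pool 1 and 0.99 without challenged pool 3. Camera at the preset correlation gave the list adjusted p of 6.47e-24 to 1.43e-19 over the fits that left out 1 pool. Subunit alpha type 5 of the proteolytic core rose by 1.80 ± 0.21 and ATPase 4 of the 26S cap, which unfolds substrates, by 1.69 ± 0.20, both called whichever pool was left out. In the MHC class I presentation list 4 of 14 genes rose, and 4 when adjusted over the list alone. They were the proteasome activator PA28 beta with 1.21 ± 0.17, the chaperone calreticulin-like 2 with 1.74 ± 0.28, tapasin, which loads peptides, with 1.20 ± 0.21 and PA28 alpha with 0.80 ± 0.19. PA28 beta was called whichever pool was left out. Calreticulin-like 2 was not called without challenged pool 1 (adjusted p = 0.0580), tapasin without control pool 2 (0.0501) or challenged pool 1 (0.0751), and PA28 alpha only without control pool 3 (otherwise up to 0.136). Camera gave an adjusted p of 6.44e-23 for proteasome, with adjusted p = 0.240 with an estimated correlation and a range over the camera alternatives of 1.14e-25 to 0.240. For MHC class I (median 0.36, 11 of 14 positive) the adjusted p was 0.00859, with adjusted p = 0.240 with an estimated correlation and a range of 0.00271 to 0.240.

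In the heat shock and ER stress list 4 of 19 genes rose, and 8 when adjusted over the list alone. HSP60, the mitochondrial chaperonin, rose by 1.97 ± 0.27, and the ER co-chaperone DNAJB11 by 1.78 ± 0.21. SEC61A, the channel into the ER, rose by 1.03 ± 0.19 and protein disulfide isomerase A4 by 1.56 ± 0.29. SEC61A was not called without challenged pool 1 (adjusted p = 0.0823) or 3 (0.0631), and PDIA4 without control pool 3 (0.0518), challenged pool 1 (0.0770) or 3 (0.0586). The list median was 0.31, and camera gave adjusted p = 0.00198, with adjusted p = 0.240 with an estimated correlation and a range over alternatives of 5.58e-04 to 0.240. All 13 genes of cell cycle and DNA replication had positive values, with a median of 0.86. Of them 5 rose, and 8 when adjusted over the list alone. Cyclin B2 and cyclin B1, which drive entry into mitosis, rose by 1.66 ± 0.20 and 1.64 ± 0.30, and the replication helicase subunit MCM2 by 0.89 ± 0.21. Cyclin B2 was called whichever pool was left out; cyclin B1 was not without challenged pool 1 (0.0803) or 3 (0.0592), and MCM2 only without challenged pool 2 (otherwise up to 0.144). The count of 5 was 2 without control pool 1, 2 without control pool 2, 3 without control pool 3, 1 without challenged pool 1, 7 without challenged pool 2 and 1 without challenged pool 3. Camera gave adjusted p = 3.07e-06, with adjusted p = 0.240 with an estimated correlation and a range of 8e-08 to 0.240. In oxidative phosphorylation, 14 of 44 genes, counted by name, rose and 1 fell, or 25 and 1 when adjusted over the list alone. ATP synthase subunits alpha 1 and delta rose by 1.15 ± 0.17 and 1.22 ± 0.21. Both lost the call without challenged pool 1 (0.0518 and 0.0675). The gene that fell, singled out after its values were seen, was an NADH dehydrogenase alpha subcomplex 12-like sequence of respiratory complex I with -0.86 ± 0.20. The count of 14 was 5 without control pool 1, 3 without control pool 2, 8 without control pool 3, 0 without challenged pool 1 and 3 without challenged pool 3, while 28 genes were higher at an unadjusted p below 0.05 with all pools and 21 by limma with an intensity trend and robust eBayes. The fallen gene was called only without challenged pool 2 among the fits that left out 1 pool. The list median was 0.54 with 43 of 44 positive, and camera gave adjusted p = 1.39e-11, with adjusted p = 0.240 with an estimated correlation and a range of 1.09e-12 to 0.240.

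Cytokines and chemokines included 11 risen and 2 fallen genes of 40, or 13 and 5 when adjusted over the list alone. Beside IL-1 beta and IL-8, the chemokine SCYA106 rose by 2.81 ± 0.22, with a median of 1.35 over its 2 sequences, of which 1 was higher. Small inducible cytokine A19 rose by 1.83 ± 0.18, from a dim control mean of 5.46. The fallen genes, singled out after their values were seen, were the chemokines SCYA126 with -1.17 ± 0.17 and SCYA104 variant 2 with -1.03 ± 0.20, of which 1 was called without control pool 2, challenged pool 1 or challenged pool 3. Interferon gamma 2, the activating cytokine of macrophages, rose by 1.42 ± 0.24 (TC18794; adjusted p = 0.0133), but not past the threshold without challenged pool 1 (adjusted p = 0.0592). Interferon gamma 1 had a difference of 0.18 ± 0.22 (adjusted p = 0.647) and TNF, another early inflammatory cytokine, 0.05 ± 0.15 (adjusted p = 0.880). The list median was 0.27, and camera gave adjusted p = 0.0177, with adjusted p = 0.240 with an estimated correlation and a range over alternatives of 0.00360 to 0.240; without challenged pool 2 it was 0.0661. In the interferon response list 2 of 8 genes rose, and 4 when adjusted over the list alone. IRF1, a transcription factor induced by interferons, rose by 2.15 ± 0.21 and guanylate-binding protein, a GTPase active against intracellular microbes, by 1.78 ± 0.15, with a median of 0.74 over its 2 sequences. The median was 0.84 with 7 of 8 positive, and camera gave adjusted p = 0.00271, with adjusted p = 0.240 with an estimated correlation and a range of 8.36e-04 to 0.240. Among pattern recognition genes 2 of 14 rose and 2 fell, over all sequences and when adjusted over the list alone. TLR5, the receptor for bacterial flagellin, rose by 2.20 ± 0.23 (adjusted p = 0.00296). A peptidoglycan recognition protein rose by 1.63 ± 0.27, TLR21, a receptor for microbial DNA, fell by 1.22 ± 0.18 and TLR20a fell by 0.88 ± 0.23. The last 3 lost the call in fits that left out 1 pool. Without challenged pool 1 the adjusted p was 0.0573 for the peptidoglycan recognition protein and 0.0528 for TLR21. For TLR20a it was 0.0581 to 0.149, whichever pool was left out. The list median was -0.24 and camera gave adjusted p = 0.344.

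Markers of neutrophils and macrophages changed in part. Of 9 neutrophil genes 3 rose, and 3 when adjusted over the list alone. A bright lysozyme c sequence rose by 2.13 ± 0.16 (CF261496_1; adjusted p = 6.66e-04), lysozyme g by 0.76 ± 0.16 (median of 3 sequences 1.34) and 5-lipoxygenase, which makes leukotrienes, by 0.70 ± 0.16. Lysozyme g was called only without control pool 2 (otherwise up to 0.0908) and 5-lipoxygenase only without challenged pool 2 (otherwise up to 0.127). The median was 0.28 with 8 of 9 positive; camera gave adjusted p = 0.00859, with adjusted p = 0.240 with an estimated correlation and a range over alternatives of 6.16e-04 to 0.240. Of 5 macrophage genes 2 rose and 1 fell, in both counts: the lysosomal protease cathepsin D rose by 1.26 ± 0.18, arginase 2 by 1.22 ± 0.18, and the representing sequence of apolipoprotein E fell by 2.48 ± 0.26. Camera gave adjusted p = 0.132 (median 0.35). Of 17 acute phase and iron proteins 3 rose, and 4 when adjusted over the list alone. Hepcidin, the hormone that limits iron export, rose by 2.23 ± 0.29 (TC17377; adjusted p = 0.00611) from a dim control level of 3.86 ± 0.42 (SD), and the list's MFAP4 sequence by 2.42 ± 0.22. Ceruloplasmin, a copper-carrying ferroxidase, rose by 0.87 ± 0.22, but was called only without challenged pool 2 among the fits that left out 1 pool (otherwise 0.0626 to 0.169). The list median was 0.02, with adjusted p = 0.344. In complement 2 of 11 genes rose and 2 fell in both counts. Complement regulatory plasma protein rose by 1.88 ± 0.19 and factor D, the protease of the alternative pathway, by 1.43 ± 0.17. The first was dim in both groups (means 4.44 and 6.31), so the size of its rise is uncertain. C1qB and C1qA, parts of the antibody-binding first component, fell by 0.95 ± 0.18 and 0.96 ± 0.24. C1qB was not called without control pool 2 (0.0593), control pool 3 (0.0514) or challenged pool 1 (0.0878), and C1qA only without challenged pool 3 (otherwise up to 0.158). The complement median was -0.11 while the mean was 0.08 and the direction of the camera test up, with adjusted p = 0.712.

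All 7 T cell genes had negative values, with a median of -0.76, and 4 fell, over all sequences and when adjusted over the list alone. T cell receptor beta, a chain of the antigen receptor, fell by 1.20 ± 0.26 (adjusted p = 0.0297), T cell receptor alpha by 0.67 ± 0.16 (0.0379) and CD4-like protein 1, a co-receptor of helper T cells, by 0.81 ± 0.21 (0.0463). The medians over all 7 sequences each of T cell receptor beta and alpha were -0.40 and -0.38. CD4-like protein 2 had -0.76 ± 0.33 (adjusted p = 0.184; median of 2 sequences -0.43). These single calls were lost in most fits that left out 1 pool. T cell receptor beta was called only without challenged pool 1 (otherwise up to 0.0912). T cell receptor alpha (0.0600 to 0.143) and CD4-like protein 1 (0.0692 to 0.138) lost the call whichever pool was left out. Such fits have fewer samples, so a lost call does not show that the call rested on that pool. Camera gave the list adjusted p = 6.67e-04, with adjusted p = 0.240 with an estimated correlation and a range over alternatives of 1.46e-04 to 0.240. All 11 B and plasma cell genes had negative values, with a median of -0.43; 1 fell in both counts. It was CD79a, a signalling chain of the B cell receptor, with -1.29 ± 0.18 (NP10015908; adjusted p = 0.00707). Its partner CD79b had -0.73 ± 0.22 (adjusted p = 0.0768, and 0.0401 without control pool 2) and the IgM heavy chain -0.14 ± 0.16 (adjusted p = 0.620), with a median of -0.33 over 17 sequences, 14 of them negative and 2 called lower. Camera gave adjusted p = 0.00329, with adjusted p = 0.240 with an estimated correlation and a range of 1.46e-04 to 0.240.

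All 8 erythroid genes had negative values, with a median of -0.59. By limma 0 of 8 passed over all sequences, and 6 fell when adjusted over the list alone; 6 were lower at an unadjusted p below 0.05, and 5 passed with an intensity trend and robust eBayes. The enzyme carbonic anhydrase had -0.79 ± 0.21 (adjusted p = 0.0502, and 0.0313 without challenged pool 2), the haem enzyme UROD -0.66 ± 0.20, the erythroid transcription factor GATA1 -0.64 ± 0.19 and the membrane anion exchanger band 3 -0.60 ± 0.18. Those counts took each gene by its representing sequence. Over all 13 sequences of carbonic anhydrase, 5 were called lower, while UROD, GATA1 and band 3 had 1 sequence each. Camera gave the erythroid list adjusted p = 0.00198, with adjusted p = 0.240 with an estimated correlation and a range of 2.73e-04 to 0.240. Of 46 cytotoxic and NK cell genes 3 rose and 3 fell, or 3 and 5 when adjusted over the list alone. Without challenged pool 1, 1 was called higher and 1 lower, and 1 was lower without control pool 2, challenged pool 2 or challenged pool 3. Granzyme N, a protease of cytotoxic granules, rose by 2.03 ± 0.27 (adjusted p = 0.00618). The list median was -0.07, with adjusted p = 0.543. No MHC class II presentation gene of 9 passed over all sequences by limma and 3 fell when adjusted over the list alone; 3 were lower at an unadjusted p below 0.05, and 3 passed with an intensity trend and robust eBayes. The invariant chain-like 2, which guides class II molecules, had -0.68 ± 0.19 (adjusted p = 0.0568) with 9 of its 18 sequences called lower, and the list median of -0.26 came with adjusted p = 0.0848. The camera test of that list passed with the trend and robust eBayes (adjusted p = 0.0362), with adjusted p = 0.240 with an estimated correlation and a range of 0.00665 to 0.240. The 87 ribosomal proteins, with 0 called by limma over all sequences or adjusted over the list alone, had a median of -0.13 and 65 negative values; 3 were lower at an unadjusted p below 0.05 and 1 passed with the trend and robust eBayes. Camera gave them adjusted p = 0.0226, with adjusted p = 0.514 with an estimated correlation and a range of 7.58e-04 to 0.514; without control pool 1, control pool 3 and challenged pool 2 it was 0.0611, 0.114 and 0.0930, with array weights 0.0622, and fry gave 0.0879. For apoptosis, 0 of 7 genes passed by limma in either count, each taken by its representing sequence. At an unadjusted p below 0.05, 4 were higher, and 2 passed with the trend and robust eBayes. The value of p53 was 0.54 ± 0.16 (adjusted p = 0.0662) and that of BAX 0.45 ± 0.17. Over all sequences of a gene, 1 of 2 for BAX and 2 of 5 for an inhibitor of apoptosis were called higher, and 0 of 4 for p53. The median was 0.48, and camera gave adjusted p = 0.0311, with adjusted p = 0.240 with an estimated correlation and a range of 0.0191 to 0.240; without challenged pools 2 and 3 it was 0.0671 and 0.0562, and over sequences above the median 0.0788 with 6 genes.

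Lists of other tissues that a kidney pool can hold were tested too. Renal tubule (6 genes, median 0.05, adjusted p = 0.932) and interrenal steroid synthesis (5 genes, median 0.24, adjusted p = 0.267) had 0 genes called by limma in either count, at an unadjusted p below 0.05 or with the trend and robust eBayes. Hepatocyte markers (12 genes, 0 called by limma in either count or with the trend and robust eBayes, 3 lower at an unadjusted p below 0.05, median -0.25) had adjusted p = 0.0665. The list passed with array weights (0.0468) and without control pool 3 (0.0371), with adjusted p = 0.240 with an estimated correlation. Of the interrenal genes 1 was called without challenged pool 2, and of the hepatocyte genes 1 without control pool 2. Among exocrine pancreas markers 2 of 9 fell in both counts, carboxypeptidase B by 0.86 ± 0.19 and pancreatic lipase-related protein 1 by 0.80 ± 0.19. Carboxypeptidase B was called only without control pool 3 (otherwise up to 0.0970) and the lipase not without any one pool (0.0595 to 0.130). The list had a median of -0.26 and adjusted p = 0.344. Of 8 skeletal muscle genes 1 fell in both counts, the fast myosin heavy chain by 1.14 ± 0.29 (adjusted p = 0.0481), which was called only without challenged pool 3 (otherwise 0.0671 to 0.167). The muscle median was 0.04, the mean -0.02 and the direction of the test down, with adjusted p = 0.839. Muscle genes set challenged pool 3 apart, where 7 of the 8 lay above the mean of challenged pools 1 and 2, with a median difference of 0.40. Thrombocytes and coagulation had 3 matched genes, 0 of them called by limma, at an unadjusted p below 0.05 or with the trend and robust eBayes, with a median of 0.01, too few for the list test, and no usable name matched the chromaffin cell list. Over all 24 tested lists, camera called 13 at the preset correlation. With an estimated correlation it called 0, with 2 at an unadjusted p below 0.05. Fry called 17, among them lists that camera at the preset correlation did not call. These were complement (0.0159, up), macrophages (0.0461, up), exocrine pancreas (0.0187, down), hepatocytes (0.0187, down) and MHC class II (0.00658, down).

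**Figure D2:**
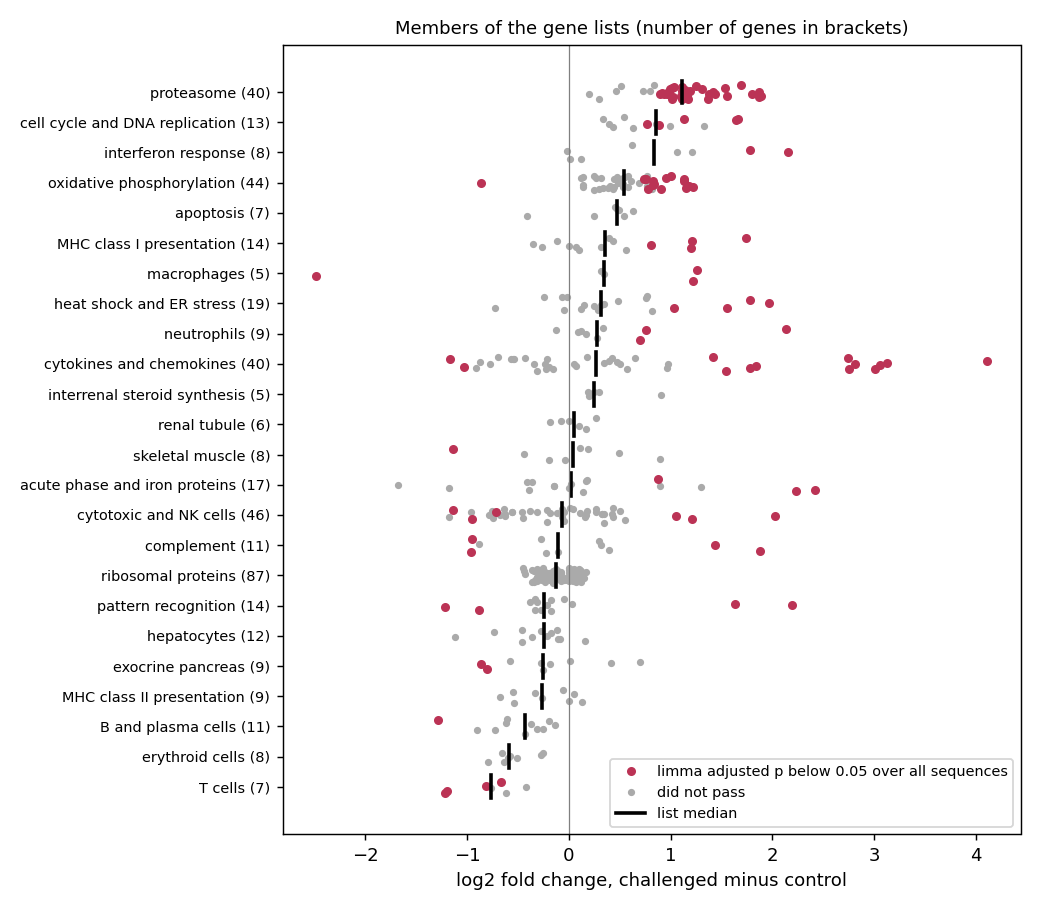
Log2 fold change, challenged minus control (horizontal axis), of each gene of the 24 tested lists, which are ordered by median on the vertical axis with their number of genes. Each point is 1 gene, red where it passed the limma threshold over all sequences and grey where it did not, and black bars are list medians; proteasome has the highest median, 1.11, and T cells the lowest, -0.76.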

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

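The first-copy, second-copy and below-14 settings were chosen after seeing the data. The count of 5712 became 8687 with array weights, 9690 at adjusted p below 0.1, 3268 with a 2-fold minimum, 724 without eBayes and 1287 with 1 sequence per gene name, where fewer sequences were tested; apart from that and the changed thresholds, the cause was not tested. Without 1 pool it ranged from 1090 to 5292 with fewer samples. It stayed within 1.5 times under the other settings, from 3896 to 7627, copies alone giving 4160 and 4253 with 2964 called in both. Of 10 splits of the samples 1 gave 5712 and the highest other 0. For lists 1 split gave 13, and every other split gave between 1 and 7. Camera at the preset correlation thus called lists in every split that mixed the groups, where 0 sequences were called. Mixed splits still hold the 2 groups unequally, so these calls give no rate of false ones. The splits are too few for a share under 0.05. Same-numbered pools deviated from their group means with r of -0.102, 0.124 and 0.364. The last, between the pools numbered 3, was the highest of any pair, while control pool 1 correlated best with challenged pool 2 (0.280). On the second principal component (20.1% of the variance) control pool 3 (68.43) and challenged pool 3 (44.23) lay apart from the other pools (-54.88 to -6.69). A factor shared by the pools numbered 3 is therefore not excluded. The replicate block gave 5096 calls, 4423 of them shared, and 13 lists.

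Camera called 13 of 24 lists, 0 with an estimated correlation, and 10 to 13 without 1 pool. The adjusted p of 0.240 that recurs with an estimated correlation is 1 value that the adjustment gave to many lists alike, so it does not rank them. Estimated correlations reached 0.507 for cell cycle and DNA replication, against the preset 0.01. MHC class I lost its call too, from adjusted p = 0.00859 to 0.240 by camera, although its estimate of 0.0112 was close to the preset. A higher correlation between genes therefore does not account for that loss, and 0.240 cannot be read as an effect of correlation alone. What else differs between the 2 forms of the test was not examined. Complement turned down above the median (adjusted p = 0.484) and above the 25th percentile (0.382), and renal tubule with array weights (0.916) and in 3 of 6 fits without 1 pool (0.227 to 0.891 over all 6). Skeletal muscle turned up with all sequences averaged (0.911) and in 2 of 6 such fits (0.399 to 0.861 over all 6). None of these passed. Of the named genes 80 of 108 were called and 45 to 66 without 1 pool, 45 without challenged pool 1, with 43 called in every such fit. The medians over all sequences of a name reversed for cytochrome c oxidase subunit IV (0.18, isoform labels dropped) and alcohol dehydrogenase (0.25). Of other values for single genes, 442 kept their side, 15 weakened, 18 strengthened and 18 moved; for lists, 225 kept it, 16 weakened and 9 strengthened. The first component held 61.7% of the variance over the brighter sequences. The deposited files of single arrays equalled the table in 105 values, and in 3528 within 0.01 on the log2 scale, where the tolerance sets the count. The values used carry no background measure, so signal over background limits dim sequences such as hepcidin.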

Other observations

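All tests in this part were chosen after the results they bear on were seen. Words in gene names were tested for groups beyond the lists. Of 464 tests on 232 words over 5536 names (hypergeometric test, Benjamini-Hochberg), 14 passed, 10 for higher and 4 for lower genes. Of these 14, 6, 7 and 7 passed without control pools 1, 2 and 3, 4, 10 and 6 without challenged pools 1, 2 and 3, and 8 with the replicate block. Names with ATPase were higher in 31 of 69 cases (44.9%, against 11.3% of other names; adjusted p = 4.95e-10), and part of them are proteasome subunits. Among 20 names of proton-transporting ATPases, the pumps that acidify lysosomes and phagosomes, 15 rose, with a median of 1.01, such as the vacuolar ATPase subunit A (1.85 ± 0.19) and a lysosomal vacuolar proton pump sequence (1.41 ± 0.19). The ATPase word passed in every other fit run, with 20 names called without control pool 1, 12 without challenged pool 1 and 19 without challenged pool 3. Of the proton-transporting names 7 to 12 of the 20 were called when 1 pool was left out: 8 without control pool 1, 9 without control pool 3, 7 without challenged pool 1 and 8 without challenged pool 3 (10 and 12 without the others). Names with interleukin were higher in 8 of 13 cases (adjusted p = 0.00192), all of them IL-1 beta or IL-8 sequences, which were already among the largest rises. The hypergeometric test takes names as independent. Several names can belong to 1 gene, as with interleukin and ATPase, so the p values of the words can be too small.

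Names with collagen, the fibrous protein of connective tissue, were lower in 8 of 16 cases (50%, against 3.35% of other names; adjusted p = 2.22e-06), with a median of -0.81; over the 22 names that contain the word in any form the median was -0.38. The 8 included collagen type I alpha 1 (-1.21 ± 0.26), alpha 2 (-1.25 ± 0.22) and alpha 3 (-1.39 ± 0.27) and type VI alpha 2 (-1.06 ± 0.19), and several names can belong to 1 gene. The median kept its sign without any one pool. The count did not: 5 were called without control pools 1 and 2 each, 4 without control pool 3, 0 without challenged pool 1 (adjusted p = 1; median -0.79) and 2 without challenged pool 3 (adjusted p = 0.280), with 8 without challenged pool 2. The range of adjusted p over the other fits was 1.5e-07 to 1.

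Muscle transcripts stood out in challenged pool 3. The muscle list's median excess of 0.40 over the other challenged pools lay at percentile 99.49 of 10000 random lists (central 95%: -0.14 to 0.32). It was led by the fast myosin light chain (2.95) and fast troponin C (2.71). The other genes lay between -0.21 (parvalbumin) and 0.95 (fast troponin T), with only 0.26 for the list's creatine kinase M. Of the 8 genes 1 was above the array median in the controls, 5 above the 25th percentile, and 0 were in another list. The 126 creatine kinase sequences, singled out like GAPDH after their values were seen, had a median level of 8.07 there against 5.74 and 6.29 in challenged pools 1 and 2 and 6.07 to 6.49 in the controls. A local array defect is argued against, since 92.06% of them were higher in both copies. In the other challenged pools these sequences did not rise: they lay -0.2629 from the controls (interval -0.31 to -0.20). That interval resampled sequences and leaves out the spread between pools, so it cannot exclude a challenge response. For the muscle list the value was -0.15 (-0.51 to 0.05), with 0.81 for its creatine kinase M, so a challenge response of that list stays open too. Muscle tissue in that pool may be the source, as a hypothesis; GAPDH, which all tissues express, was 2.03 higher there over 20 sequences.

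A range over 4 on the log2 scale between pools of 1 group was found in the first copy of 82 sequences, 33 within the controls and 52 within the challenged pools. By limma 0 of them were called between groups, with 22 at an unadjusted p below 0.05. As the mean of both copies, CK420624_1 had 12.82, 12.89 and 13.01 in the controls and 4.06, 12.21 and 10.34 in the challenged pools. All of the 82 (100%) differed the same way by over 2 in the second copy, which argues against a local array defect, and 40.24% differed within the controls, which argues against the challenge for those only. For the 49 that differed within the challenged pools alone it stays open: in 26.53% (interval 16.2% to 40.3%) all 3 lay on one side of the controls, against 32.8% of all sequences. MHC names were 7 of the 19 named ones, against 1.12% of other named sequences (odds ratio 51.61, Fisher's exact p = 1.19e-09), consistent with inherited differences between the pooled fish. Fisher's test took sequences as independent, while several can belong to 1 MHC gene, so its p can be too small. Fish genotypes were not analysed here, so inherited differences stay a hypothesis.

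The genes of the T cell and erythroid lists all had negative values, but both lists had adjusted p = 0.240 by camera with an estimated correlation. Of the erythroid genes 0 of 8 passed by limma, each taken by its representing sequence. Dilution by other cells should lower kidney tubule and interrenal genes alike. The 14 T cell and erythroid genes above the array's 25th percentile had a median of -0.65 (range -1.216 to -0.254). The 7 tubule and interrenal ones had 0.19 (range -0.186 to 0.295), a difference of -0.8315 (bootstrap interval -1.01 to -0.59). The lists were chosen after their values were seen, and the interval resampled genes, not pools. That it excludes 0 was therefore set in advance, and it does not decide on dilution. For the same reason that interval does not decide on 1 scale factor per array, which moves all genes alike. Other values argue against such a factor for these 14 genes. The median log2 fold change of all sequences was only -0.036. Centring on array medians, which removes such a factor, left all 24 lists with the same direction and call. Scaling that depends on intensity was tested only by renewed quantile normalisation, which also left direction and call of all 24 lists unchanged. Fewer T cells and erythroid cells, or lower expression per cell, may each account for the negative values, and neither was tested. Vaccination and challenge were not separated by the design.

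Among sequences called by limma, the largest changes were in those without a usable name. TC17930 rose by 7.46 ± 0.27 and BE468955_1 by 7.10 ± 0.21, while CK410713 fell by 4.08 ± 0.24 and CATF0002S00025908 by 3.74 ± 0.31. Usable names were carried by 13 of the 50 largest rises and 7 of the 50 largest falls. The SD of log2 fold changes was 0.711 for sequences with means between 8 and 10 and 0.226 above 14, where 40 of 3551 sequences (1.13%) were called.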
